A study of Xenopus laevis with 24 samples.

How the data were processed

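RNA was taken from tissue explants of *Xenopus laevis* embryos kept at 16 °C. Per the labels' protocols, dorsal marginal zone (DMZ) explants were cut at stage 10.5 (50 isolated, 5 or 6 collected per time point), 5 ventral marginal zone (VMZ) explants were cut at stage 10.5, and 20 animal caps were cut at stage 8. Total RNA was extracted with TRIzol, and libraries were made at a core facility with a standard Illumina preparation. The replicate numbers 1 and 2 are in the labels.

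The authors' deposited count table holds 1 whole-number count per gene model and library, for 31694 gene models and 24 libraries. Trim Galore, kallisto and DESeq2 are named per the submitters' processing notes, and their versions, their order and the genome build are not given in the sources used here. kallisto divides a read that matches several transcripts among them by estimation, so counts of near-identical L and S copies, and of other paralogs, depend on that division. Strand handling is likewise not given in the sources used here, so overlapping antisense genes were not told apart. A further table of the authors' deposited values gives 1 regularised log2 value per group, an adjusted p-value and a cluster number for 13913 gene models, of which the largest listed adjusted p is 0.000999685. What the adjusted p tests is not given in the sources used here. These values were used only to compare the lists of changing genes. No reference genome was used here, and gene names are those of the authors' deposited tables. Of the 31694 gene models, 10759 carry an L name and 7757 an S name, and 844 share their name with another model.

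Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Gene models were kept by filterByExpr with groups (minimum count 10, minimum total count 15), which left 31349. Library sizes were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 24 libraries with robust empirical Bayes, which leaves 12 residual degrees of freedom, and the biological coefficient of variation was 0.33. With 2 libraries per group, the spread is estimated mostly from the other groups. Each comparison was tested with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method over all tested gene models. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. It is a rough guide where a group has few counts. CPM values use the TMM-scaled library sizes, and log CPM for the principal components used a prior count of 2. All p-values are two-sided.

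The comparisons were DMZ with VMZ, DMZ with animal cap and VMZ with animal cap at stage 11, DMZ stage 18 with 11, 14 with 11 and 18 with 14, the 9 steps between neighbouring stages, any change over the 10 stages, and stage 18 with 12 for the genes that differed between regions at stage 11. For the first 6 comparisons, 30 gene lists fixed by symbol before the data were examined were tested with camera, with the correlation between genes estimated from the data and Benjamini-Hochberg adjustment over the 30 lists. Camera compares the members of a list with all other genes. Members called were counted over all genes and adjusted over the list alone. Many lists share members. L to S ratios were tested with limma (trend) on log2 of the L count plus 0.5 over the S count plus 0.5, for the 5024 pairs with both members past the filter.

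The genes named were chosen by a rule fixed before the data were examined, along with the groups, tests, lists and other settings to try. The rule takes the 6 called genes of largest rise and the 6 of largest fall in each of the first 6 comparisons, with a gene symbol, at least 5 CPM in the higher group and no overlap between the libraries of the groups. It adds up to 4 called members of smallest p per gene list, the 6 genes of largest range for any change, and a set of anchor genes whatever their result. Only part of the genes that the rule takes are named below. The anchor genes are likewise not all given, nor given in every comparison. Genes outside the rule are said to be chosen after their values were seen.

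Groups were given the same replicate numbers, and the numbers paired the samples: for all 66 pairs of groups, the correlation across genes of the deviations of same-numbered libraries from their group means was over 0.1 (lowest 0.24, median 0.41, highest 0.67). The pairing comes from this check and not from the labels. A fit with the replicate number as a block was therefore set beside a result where it changed the call or moved a printed count over all genes by over 1.5 times. The other settings, fixed before the data were examined, were RLE size factors, upper quartile scaling, no filter and a stricter filter (at least 1 CPM in 4 libraries), DESeq2 1.42.0, the replicate block, a fit of only the groups compared, no robust step, glmTreat against a fold of 1.5, L and S counts summed, and leaving out each library in turn. For lists they were a preset correlation of 0.01 and fry, and for L to S ratios a pseudocount of 5 and a mean of at least 50 counts. Thinning every library to the smallest total (7.38 M counts) was chosen after seeing the data.

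Library totals ranged from 7.38 to 39.8 M counts (median 31.9), and the 10 most abundant genes held 2.88 to 6.56% of a library. Replicates correlated at 0.942 to 0.978 (Pearson, log CPM, across genes). Where a group had 0 counts of a gene, the fold is given as a lower limit against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact Clopper-Pearson 95% interval. These limits and intervals cover counting error only. Each test was tested on simulated counts of the same libraries. At a true fold of 4, the tests of DMZ with VMZ, of stage 18 with 11 and of stage 18 with 17 recovered 55, 52 and 51% of 100 changed genes, and at a fold of 2 they recovered 10, 8 and 9%. The test of any change recovered 39% at a fold of 4 and 0% at a fold of 2, and the L to S test 56 and 7%. Changed genes were drawn from those with an average log2 CPM above 0. Changed pairs were drawn from those with a mean of at least 50 counts for each copy. L and S copies were simulated independently, so deviations shared by both in a library, which would cancel in the ratio, were absent. The L to S recovery may therefore not hold for real pairs. Among unchanged genes, 1 of 31149 was called in DMZ with VMZ and 5 of 31109 in stage 18 with 11. Camera gave an adjusted p of 3.63e-08 for a simulated list of 40 genes changed by a fold of 2 and called 0 of the unchanged lists. The simulated genes were drawn independently, so this does not show how camera performs on lists whose members are correlated.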

Results

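Transcript levels were measured by RNA sequencing in explants of *Xenopus laevis*, the African clawed frog, an allotetraploid that carries an L and an S copy (homeologs) of many genes. The dorsal marginal zone (DMZ) is the dorsal equatorial tissue of the gastrula and holds the Spemann organizer. Explants of it known as Keller explants extend in culture by convergent extension. Per the labels, DMZ explants were cut at stage 10.5 and collected, 5 or 6 per time point, when sibling embryos reached each of 10 stages from 11 to 18. Ventral marginal zones (VMZ, 5 explants) cut at stage 10.5 and animal caps (20 explants) cut at stage 8, the prospective ectoderm, were collected at stage 11. There were 12 groups of 2 libraries, 24 in all. The total count was 7.38 M in DMZ stage 11 replicate 2 and 14.6 M in DMZ stage 17 replicate 1, and it lay between 21.9 and 39.8 M in the other libraries. The labels number the replicates without saying whether they came from separate clutches or days, so p-values measure only the spread between these samples. Levels are CPM (counts scaled to library size) given as mean ± SD (n = 2), log2 fold changes are given ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. L and S copies were counted as separate genes, and how reads were split between near-identical copies is uncertain.

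The first principal component of log2 CPM held 54.1% of the variance and ordered the DMZ libraries of each replicate number by stage, from -96.9 and -151 at stage 11 to 142.6 and 141.6 at stage 18. Across the numbers the order was not kept, since replicate 2 of stage 11.5 (-119) lay below replicate 1 of stage 11. The second held 11.3%, and within each of the 12 groups replicate 1 lay above replicate 2 on it. It did not separate the replicate numbers across groups, since replicate 1 of DMZ stage 18 (-26.5) lay below replicate 2 of DMZ stage 12 (-18.4).

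**Figure D1:**
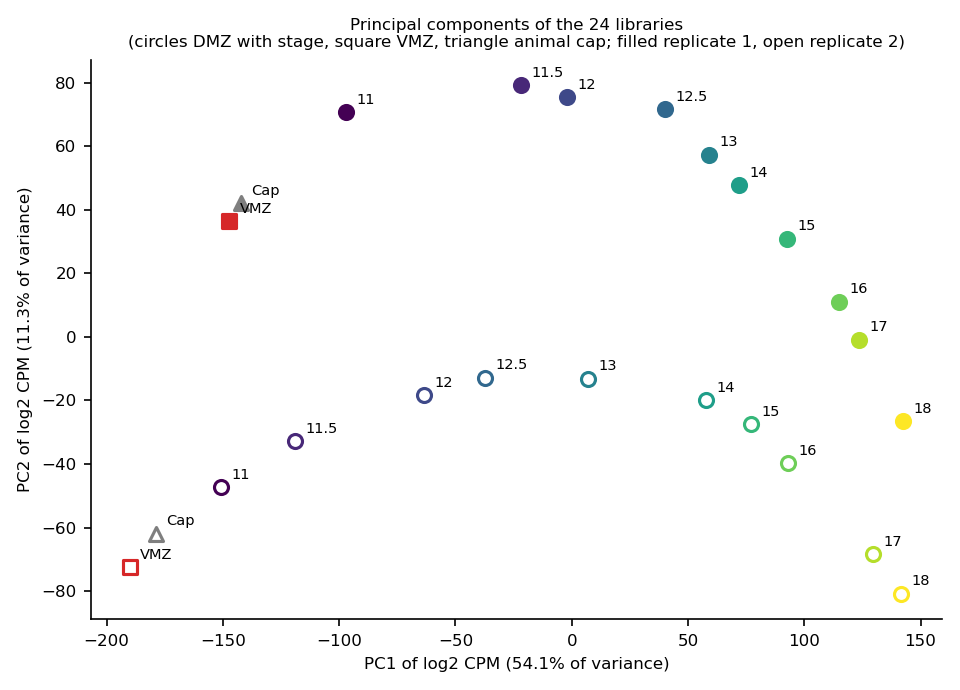
Each point is 1 library placed by its first (54.1% of variance) and second (11.3%) principal component of log2 CPM, with circles for DMZ labelled by stage, squares for VMZ, triangles for animal cap, filled symbols for replicate 1 and open symbols for replicate 2. Within each replicate number the DMZ stages run along the horizontal axis, and replicate 1 lies above replicate 2 in every group.

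The comparison of DMZ with VMZ at stage 11 addressed which transcripts set the dorsal marginal zone apart from the ventral one. On the first principal component, VMZ replicates 1 and 2 (-147.3 and -190) lay below the DMZ libraries of the same number (-96.93 and -151). Lower values there belong to earlier DMZ stages within each replicate number. How far differences between the regions reflect a difference in position along the course was not tested. Genes of the Spemann organizer were higher in the DMZ. *chrd.L*, which encodes the secreted BMP antagonist Chordin, stood at 386 ± 140 CPM in the DMZ and 1.11 ± 0.78 in the VMZ (log2 fold change 8.47 ± 0.53, adjusted p = 4.67e-07). Its neighbour in name *chrd.2.L* was at 279 ± 110 against 0.403 ± 0.0038 (9.42 ± 0.44). *admp.S*, which encodes a BMP-family ligand of the organizer, was at 56.3 ± 34 against 0.571 ± 0.24 (6.58 ± 0.61). *nog.L*, which encodes the BMP antagonist Noggin, was at 12.9 ± 5.7 against 0.575 ± 0.2 (4.43 ± 0.37). In the other direction, *wnt8a.L*, which encodes a ventrolateral Wnt ligand, was at 1.16 ± 0.35 in the DMZ and 74 ± 55 in the VMZ (-6.07 ± 0.94, adjusted p = 0.00217).

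Of the 33 dorsal organizer genes tested, 21 were higher in the DMZ, 0 lower and 12 not called, and 25 were higher when adjusted over the list alone (camera adjusted p = 0.000831). They included *pkdcc.2.L* (34 ± 2.2 against 0.743 ± 0.25 CPM), *otx2.L* (64.2 ± 26 against 1 ± 0.62) and *not.S* (155 ± 26 against 35 ± 12), a notochord homeobox gene. Among 28 notochord genes 9 were higher and 0 lower (10 higher adjusted over the list alone, camera adjusted p = 0.00601). Of the 28, 22 are also in another list, and *chrd*, *nog*, *not* and *foxa4* genes are in the dorsal organizer list too. The calls of the notochord and dorsal organizer lists are therefore not independent. Hedgehog genes showed 8 higher and 2 lower of 27 (15 and 2 adjusted over the list alone, camera adjusted p = 0.00633). The ligand gene *shh.S* was at 22.3 ± 8.5 against 0.278 ± 0.042 CPM (6.33 ± 0.54). Its homeolog *shh.L* had 2 counts in the VMZ and a ratio of 154 (95% counting interval 41.8 to 1280). The transducer gene *gli1.S* was at 31 ± 3.5 against 2.25 ± 0.34. The 2 lower members were *cdon.L* (-0.77 ± 0.18) and *cdon.S* (-1.03 ± 0.21), which encode a Hedgehog co-receptor, named after their values were seen. Neither was called without VMZ replicate 2 (adjusted p = 0.19 and 0.104) or without DMZ stage 11 replicate 2 (0.0872 and 0.0997), nor was *cdon.L* without DMZ stage 11 replicate 1 (0.133).

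Neural plate genes moved the same way, with 16 of 48 higher and 0 lower (26 and 1 adjusted over the list alone, camera adjusted p = 0.00633). *lrig3.S* stood at 208 ± 10 CPM against 29 ± 8.5, *foxd4l1.1.S* at 119 ± 22 against 12 ± 4.2, and *irx2.L* had a log2 fold change of 2.83. Of 34 Notch genes 7 were higher and 0 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.0381), led by *hes7.1.L* at 37.7 ± 5 against 1.65 ± 0.63 CPM. With the replicate number as a block it had 11 higher and 1 lower and was not called (adjusted p = 0.104). The anterior neural list, which shares *otx2* with the organizer list, had 6 of 42 higher (8 adjusted over the list alone, 10 over all genes with the replicate block) and was not called with an estimated correlation (adjusted p = 0.267). DESeq2 called 25 neural plate and 11 Notch genes higher.

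The ventral and BMP list had 0 higher and 2 lower of 45, *wnt8a.L* and *wnt8a.S* (5 lower adjusted over the list alone, and over all genes 6 with the replicate block and 10 with DESeq2), and was not called with an estimated correlation (adjusted p = 0.301). The ventral genes *ventx1.2.L* and *szl* stood higher in both VMZ libraries than in either DMZ library without passing the edgeR test. *ventx1.2.L* was at 7.96 ± 1.1 CPM in the DMZ and 68.5 ± 24 in the VMZ (-3.09 ± 1, adjusted p = 0.108, and 0.0103 with DESeq2), and *szl*, which encodes the chordin protease inhibitor Sizzled, at 13.8 ± 5.4 against 81.6 ± 25 (adjusted p = 0.351). The libraries overlapped for *bmp4.L*, at 60 ± 23 against 78.1 ± 16 (adjusted p = 0.636). Of 41 pan-mesodermal genes, 3 were higher and 2 lower (4 and 5 adjusted over the list alone, 5 lower with the replicate block or DESeq2, camera adjusted p = 0.802). *t.S*, a Brachyury gene, was at 374 ± 120 CPM in the DMZ and 235 ± 140 in the VMZ (adjusted p = 0.437). The 3 gene models named *t2.S*, which the list does not hold, were called higher in the DMZ. Their log2 fold changes were 2.405, 3.901 and 4.08 (adjusted p = 0.0118, 0.00375 and 0.00121), and they are named here after these values were seen. The immediate early gene *fos.S* was lower in the DMZ, at 30.9 ± 4.8 against 114 ± 18 (-1.88 ± 0.33).

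Genes of planar cell polarity, the pathway that orients convergent extension, had 7 higher and 3 lower of 57 (9 and 3 adjusted over the list alone) and were not called with an estimated correlation (adjusted p = 0.514). The median change of this list was near 0 and changed sign with upper quartile scaling (-0.05 against 0.05). The receptor gene *fzd7.L* was higher, at 899 ± 24 CPM against 362 ± 53 (1.31 ± 0.19, adjusted p = 0.00109). Not called were *vangl2.L* (216 ± 57 against 163 ± 28, adjusted p = 0.351), *wnt11b.L* (278 ± 50 against 226 ± 91, adjusted p = 0.71) and *prickle1.L* (228 ± 43 against 194 ± 51, adjusted p = 0.674).

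Across 31349 gene models, 701 were higher in the DMZ and 284 lower (71.2% higher), of which 564 and 208 differed by at least 2-fold. Upper quartile scaling gave 956 and 207 (82.2% higher). Of 59 maternal transcripts 0 were higher and 5 lower (1 and 11 adjusted over the list alone, 1 and 14 with the replicate block, 1 and 8 with DESeq2, camera adjusted p = 0.267). Here the VMZ libraries differed from each other, though over the maternal list the median log2 difference of replicate 2 over replicate 1 was 0.26. The lists of largest difference between them were pan-mesoderm (-1.26), presomitic (-1.2) and endoderm (-1.07). *ccnb5.L* stood at 1.97 CPM in VMZ replicate 1 and 26.8 in replicate 2, *cpeb1.L* at 1.51 and 19.8, and *ccna1.L* at 18.5 and 82, against 7.83 and 13.4 for *ccna1.L* in the DMZ (genes chosen after their values were seen). Without VMZ replicate 2, *ccnb5.L* and *cpeb1.L* were not called (adjusted p = 0.308 and 0.845), nor were they without DMZ stage 11 replicate 1 (0.159 and 0.285) or 2 (0.0665 and 0.146). *ccna1.L* was called with the replicate block (adjusted p = 0.00636) and with L and S counts summed (0.00845). The DMZ libraries differed in endoderm genes, picked out here after their values were seen. *sox17a.S*, which is also an anchor gene, stood at 0.576 CPM in replicate 1 and 11.3 in replicate 2, and *mixer.L* at 2.41 and 23.9. The organizer gene *gsc.L*, an anchor fixed in advance, was at 2.27 CPM in DMZ replicate 1 and 32.1 in replicate 2, with an adjusted p of 0.0367 that rose to 0.192 without DMZ stage 11 replicate 2, 0.118 without VMZ replicate 1, 0.301 without VMZ replicate 2 and 0.0698 with L and S counts summed. The total of 985 calls became 2714 with the replicate block, 2251 with DESeq2, 285 against a fold of 1.5 and 0 when only these 4 libraries were fitted. It fell to 210 without VMZ replicate 2 and 379 without DMZ stage 11 replicate 1, where *wnt8a.L* and *wnt8a.S* were no longer called (adjusted p = 0.0514 and 0.0561). The lower calls became 45 without VMZ replicate 2 and 598 without VMZ replicate 1, and 50 and 89 without DMZ stage 11 replicate 1 or 2 (58.3 to 87% higher over these).

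**Figure D2:**
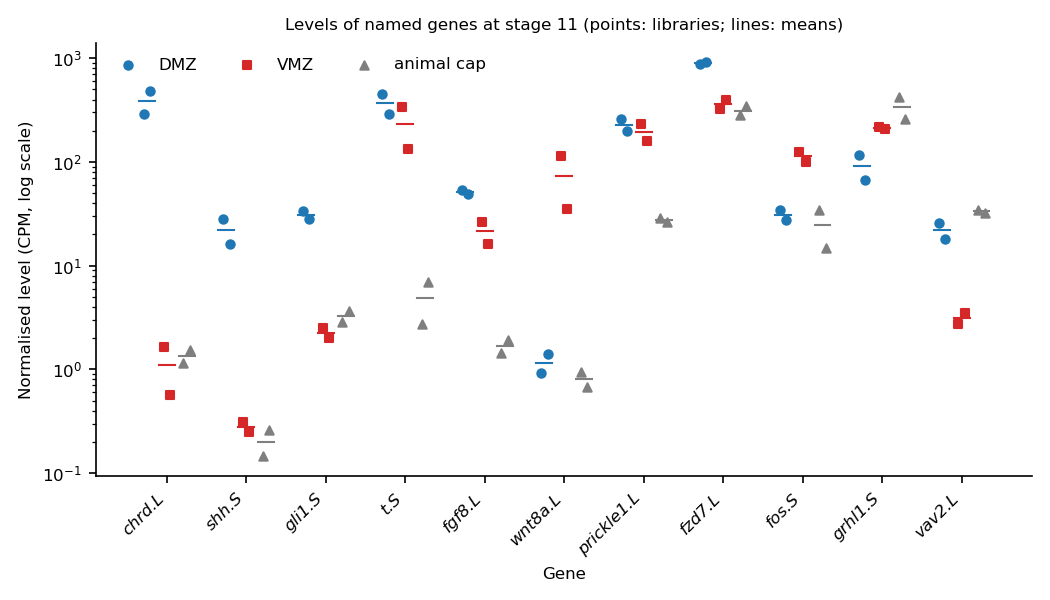
Level of 11 genes at stage 11 in CPM on a log axis, with 1 point per library, a short line at each group mean, blue circles for DMZ, red squares for VMZ and grey triangles for animal cap. *chrd.L* stood at 386 CPM in DMZ and 1.11 in VMZ, *wnt8a.L* at 1.16 and 74, and *t.S* at 374 and 235 with 4.84 in animal cap.

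The comparison of DMZ with the animal cap set mesoderm and neurectoderm apart from prospective epidermis. Caps were cut at stage 8 and DMZ explants at stage 10.5, with 20 and with 5 or 6 explants collected. Differences of tissue therefore cannot be told apart from those of cutting stage, time in culture or explant number. *foxa4.S*, a forkhead gene of the organizer and notochord, stood at 198 ± 44 CPM in the DMZ and 0.254 ± 0.051 in the cap (log2 fold change 9.58 ± 0.7, adjusted p = 9.99e-07). *t.S* was at 374 ± 120 against 4.84 ± 3 (6.27 ± 0.53) and *fgf8.L*, which encodes a growth factor of the marginal zone, at 51 ± 3.3 against 1.69 ± 0.34 (4.91 ± 0.29). Of 3 gene models named *t2.S*, 1 (gene44007) had 0 counts in both cap libraries and was at least 147-fold higher in the DMZ against a floor of 3 counts over the group, and the log2 fold changes of the other 2 were 7.75 and 7.49. *rgs16.S*, also with 0 counts in the cap, was at least 146-fold higher. The transcription factor gene *grhl1.S* of the epidermis was lower, at 92.2 ± 36 against 341 ± 110 (-1.88 ± 0.29, adjusted p = 0.00127).

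FGF pathway genes were higher in the DMZ for 23 of 32 members and lower for 2 (27 and 2 adjusted over the list alone, camera adjusted p = 0.000257). The feedback regulators *spry2.S* and *spry1.S* had log2 fold changes of 4.22 and 3.47, and the 2 lower members were *fgfr4.L* (-1.48 ± 0.34) and *fgfr4.S* (-1.24 ± 0.25), which encode a receptor. The dorsal organizer list had 20 of 33 higher and 0 lower (29 adjusted over the list alone, camera adjusted p = 0.000257). The notochord list had 12 of 28 and 0 (12 adjusted over the list alone, camera adjusted p = 0.000257), and the pan-mesoderm list 19 of 41 and 0 (27 adjusted over the list alone, camera adjusted p = 0.000895). *vegt.L*, a T-box gene of mesoderm and endoderm, was at 213 ± 84 CPM against 7.76 ± 4.2, and *lhx1.S* at 110 ± 41 against 0.868 ± 0.87. Wnt response genes were higher for 12 of 34 (19 adjusted over the list alone, camera adjusted p = 0.00301), among them *cdx2.S* at 74.4 ± 7.8 against 1.75 ± 0.53. Hedgehog genes were higher for 10 of 27 (13 adjusted over the list alone, camera adjusted p = 0.00212).

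Planar cell polarity genes differed here, with 11 of 57 higher and 2 lower (16 and 3 adjusted over the list alone, 4 lower with the replicate block, camera adjusted p = 0.0127). *wnt11b.L*, which encodes a non-canonical Wnt ligand, stood at 278 ± 50 CPM against 12.4 ± 1.2 (4.49 ± 0.38), *prickle1.L* at 228 ± 43 against 27.7 ± 1.7 (3.04 ± 0.25), *prickle1.S* at 172 ± 24 against 13.4 ± 0.42 and *fzd7.L* at 899 ± 24 against 313 ± 42, while *vangl2.S* was at 84.3 ± 9.3 against 74.9 ± 6.5 (adjusted p = 0.892, and 0.0271 with L and S counts summed). The 2 lower members were *dvl3.L* (-1.52 ± 0.34) and *vangl1.S* (-1.81 ± 0.39). Neural plate genes were higher for 20 of 48 and lower for 0 (26 adjusted over the list alone, camera adjusted p = 0.000553), with *foxd4l1.1.L* at 117 CPM against 0.32. Epidermal and non-neural ectoderm genes were lower for 10 of 51 and higher for 1 (25 and 1 adjusted over the list alone, camera adjusted p = 0.0115). The higher member was the keratin gene *krt18.S* (1.75 ± 0.38), and *dlx6.L* was lower by a log2 fold change of -1.75. DESeq2 called 23 of this list lower. The keratin gene *krt12.S*, at 119 ± 110 against 511 ± 390, was not called (adjusted p = 0.147) but was with the replicate block (0.0424), with DESeq2 (0.0251) and without DMZ stage 11 replicate 1 (0.045).

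The retinoic acid list (5 of 32 higher, 0 lower, 10 higher adjusted over the list alone, camera adjusted p = 0.0119) was led by the retinoic acid hydroxylase gene *cyp26a1.L*, at 64.8 ± 23 CPM against 7.26 ± 0.21. The nodal list had 9 of 31 higher and 2 lower (16 and 4 adjusted over the list alone, camera adjusted p = 0.0399), with the feedback inhibitor gene *lefty.L* at 38.2 ± 0.66 against 2.6 ± 0.22. The Notch list had 8 of 34 higher and 1 lower (9 and 2 adjusted over the list alone, 2 lower with the replicate block, camera adjusted p = 0.0119), and the extracellular matrix list 6 of 45 and 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0475). The presomitic list had 7 of 42 higher and 1 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.0478) and was not called with the replicate block, which gave 2 lower (adjusted p = 0.0887). *hes7.1.L*, in both the Notch and the presomitic list, was at 37.7 ± 5 against 0.973 ± 0.4 CPM. In the cadherin and adhesion list 11 of 56 were higher and 1, *efna1.S*, lower (17 and 3 adjusted over the list alone, 2 lower with the replicate block), and the list was not called with an estimated correlation (adjusted p = 0.0593). DESeq2 called 9 retinoic acid and 12 presomitic genes higher, and 15 nodal genes higher and 4 lower.

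The members named because they went against their list were chosen after their values were seen. Without animal cap replicate 2 the calls of *fgfr4.L* (adjusted p = 0.279), *fgfr4.S* (0.0877) and *dvl3.L* (0.143) were lost, and without animal cap replicate 1 those of *vangl1.S* (0.156) and *krt18.S* (0.184). Without DMZ stage 11 replicate 1 the calls of *fgfr4.L* (0.15), *fgfr4.S* (0.111), *dvl3.L* (0.156), *vangl1.S* (0.069) and *krt18.S* (0.0541) were lost, and without replicate 2 those of *fgfr4.L* (0.117), *dvl3.L* (0.1), *vangl1.S* (0.112) and *krt18.S* (0.0817). With L and S counts summed those of *vangl1.S* (0.0723) and *krt18.S* (0.158) were lost.

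In all, 781 gene models were higher in the DMZ than in the cap and 225 lower (77.6% higher), of which 705 and 199 differed by at least 2-fold. The 1006 calls became 1692 with the replicate block, 1645 with DESeq2 and 513 against a fold of 1.5. They became 193 when only these 4 libraries were fitted, 489 and 575 without animal cap replicate 1 or 2, and 656 and 744 without DMZ stage 11 replicate 1 or 2. The lower calls became 67 and 173 without animal cap replicate 1 or 2, and 129 and 65 without DMZ stage 11 replicate 1 or 2 (69.9 to 91.3% higher over these).

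Genes higher in the DMZ than in both other tissues numbered 370, and 41 were lower than in both. *chrd.L*, *shh.S*, *gli1.S* and *fzd7.L* were among the 370. Both comparisons use the same DMZ libraries. In 5 simulations with no effect edgeR called at most 1 gene, so the overlap of calls was 0. Lists of the observed sizes taken there by p-value shared 112 to 134 higher and 61 to 75 lower genes, more than observed for the lower ones. Independent lists of these sizes would share 17.5 higher and 2.04 lower genes. Part of the overlap may come from the shared controls, which hold only 2 libraries and were not split.

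The comparison of VMZ with the animal cap set ventral mesoderm apart from prospective ectoderm. Caps were cut at stage 8 (20 explants) and VMZ at stage 10.5 (5 explants). Here too tissue cannot be told apart from cutting stage, time in culture or explant number. *wnt8a.L* stood at 74 ± 55 CPM in the VMZ and 0.81 ± 0.19 in the cap (log2 fold change 6.51 ± 0.94, adjusted p = 0.00152), *t.S* at 235 ± 140 against 4.84 ± 3 (5.59, adjusted p = 2.95e-05), and *wnt11b.L* at 226 ± 91 against 12.4 ± 1.2 (4.19, adjusted p = 2.66e-05). *prickle1.L* was at 194 ± 51 against 27.7 ± 1.7 (2.81, adjusted p = 2.55e-05). *vav2.L* was lower, at 3.11 ± 0.53 against 33.3 ± 1.7 (-3.41 ± 0.3), as was the fringe gene *lfng.L* (26.8 ± 2.5 against 104, -1.95 ± 0.23).

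Of 41 pan-mesoderm genes, 25 were higher in the VMZ and 0 lower (34 adjusted over the list alone, camera adjusted p = 0.000753). VMZ replicate 2 lay below replicate 1 over the pan-mesoderm (median log2 difference -1.26), FGF (-0.94) and Wnt (-0.65) lists. FGF pathway genes were higher for 17 of 32 and lower for 1 (27 and 2 adjusted over the list alone, 2 lower with the replicate block, camera adjusted p = 0.00152), with *fgf8.L* at 21.5 ± 7.3 against 1.69 ± 0.34 CPM. The lower member, *fgfr4.S*, was named after its values were seen and lost its call without animal cap replicate 2 (adjusted p = 0.102) or VMZ replicate 1 (0.103). Wnt response genes were higher for 11 of 34 and lower for 0 (17 adjusted over the list alone, camera adjusted p = 0.00517), among them *cdx2.S* at 62 ± 27 against 1.75 ± 0.53. The dorsal organizer list had 4 higher (*foxa4.L*, *foxa4.S*, *lhx1.L* and *lhx1.S*) and 1 lower of 33 (12 and 7 adjusted over the list alone, camera adjusted p = 0.318), and DESeq2 called 9 higher and 4 lower. *chrd.L* was not called (1.11 ± 0.78 against 1.35 ± 0.27, adjusted p = 0.953). The ventral and BMP list had 9 of 45 higher and 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.589). The endoderm list had 4 of 32 higher over all genes (10 with the replicate block, 14 with DESeq2) and 18 adjusted over the list alone, and was not called with an estimated correlation (adjusted p = 0.0749). With the replicate block the nodal list (7 of 31 higher, 11 with the block or DESeq2, 13 adjusted over the list alone, adjusted p = 0.0653 without and 0.0325 with the block), the planar cell polarity list (5 of 57 higher, 7 adjusted over the list alone, 0.0717 and 0.02) and the maternal list (3 of 59 higher, 5 with the block, 3 adjusted over the list alone, 0.113 and 0.0425) were called as well.

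There were 226 higher and 98 lower gene models (69.8% higher), and upper quartile scaling gave 192 and 158 (54.9% higher). Maternal *ccna1.L* (18.5 and 82 CPM in VMZ replicates 1 and 2) moved with the replicate here too, and in the cap it was at 12.8 and 16.2. It was called with L and S counts summed (adjusted p = 0.0435). The 324 calls became 867 with the replicate block, 902 with DESeq2, 159 against a fold of 1.5, 0 when only these 4 libraries were fitted, and 133 and 179 without animal cap replicate 1 or 2. The lower calls became 37 without animal cap replicate 1 and 43 without VMZ replicate 2.

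**Figure D3:**
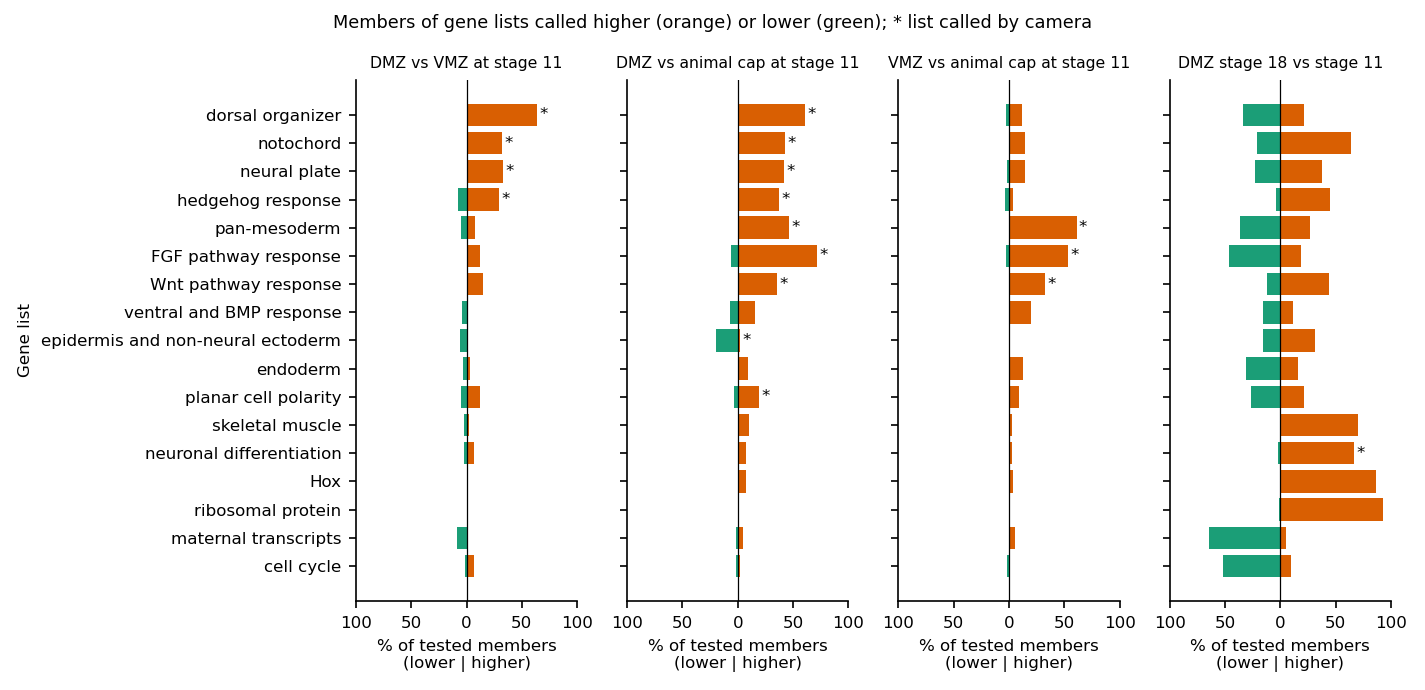
Share of the tested members of 17 fixed gene lists called higher (orange, to the right) or lower (green, to the left) in 4 comparisons, in percent of members, with an asterisk where camera called the list. In DMZ vs VMZ, 21 of 33 dorsal organizer genes were higher, and from stage 11 to 18 of the DMZ 118 of 127 ribosomal protein list members rose and 38 of 59 maternal transcripts fell.

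The comparison of DMZ explants at stage 18 with stage 11 spans the whole course. Some genes of muscle, notochord and neurons rose from under 1 CPM. *actc1.L*, a sarcomeric actin gene, rose from 0.0678 ± 0.096 to 241 ± 61 CPM (log2 fold change 11.11 ± 1.32, adjusted p = 1.72e-05), the sarcoplasmic calcium pump gene *atp2a1.L* from 0.251 to 240 ± 17 (9.58 ± 0.89). The notochord collagen gene *col2a1.S* rose from 0.284 ± 0.22 to 116 ± 27 (8.35 ± 1.09), and the neuronal tubulin gene *tubb2b.S* from 0.817 ± 0.29 to 59.4 ± 12 (6.29 ± 0.7). Among the genes that fell, *gdf9.L*, an oocyte growth factor gene, went from 73.1 ± 2.4 to 3.95 ± 0.51 (-4.21 ± 0.26, adjusted p = 1.71e-07), and the nodal co-receptor gene *tdgf1.3.L* from 235 ± 20 to 9.68 ± 0.039 (-4.60 ± 0.27).

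Several genes had no counts at 1 end. *thbs4.S* (53.1 ± 8.1 CPM at stage 18), the forkhead gene *foxe1.S* (14.1 ± 7.5) and the proneural gene *neurod4.L* (11.4 ± 0.74) had 0 counts at stage 11 and were at least 662-fold, 177-fold and 142-fold higher. The mesendodermal homeobox genes *mix1.S* and *bix1.2.L* had 0 counts at stage 18 and were at least 208-fold and 144-fold lower than at stage 11. *mix1.L*, with 1 count at stage 18, had a ratio of 778 (95% counting interval 139 to 30800), and *bix1.3.L*, with 2 counts, a ratio of 473 (130 to 3920). At stage 11 *mix1.L* stood at 8 CPM in replicate 1 and 22.3 in replicate 2.

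Neuronal differentiation was the list called by camera, with 28 of 42 members higher at stage 18 and 1 lower (30 and 1 adjusted over the list alone, adjusted p = 0.0383). The lower member was *lhx3.S*, named after its values were seen, which lost its call without DMZ stage 11 replicate 2 (adjusted p = 0.0505) or stage 18 replicate 1 (0.0549) and with L and S counts summed (0.488). *ebf2.S*, a transcription factor gene of early neurons, rose by 5.64 ± 0.5 on the log2 scale to 14 ± 1.9 CPM. Of 40 skeletal muscle genes 28 rose and 0 fell (29 adjusted over the list alone), but the list was not called with an estimated correlation (adjusted p = 0.0644). *actc1.S* reached 304 ± 28 CPM from 2.25 ± 1.2. The notochord list had 18 rising and 6 falling of 28 (18 and 6 adjusted over the list alone, adjusted p = 0.193 with an estimated correlation). The extracellular matrix list had 23 rising and 3 falling of 45 (23 and 3 adjusted over the list alone, 8 falling with the replicate block, adjusted p = 0.0644 with an estimated correlation), led by *hapln3.L* (4.32) and *sparc.L* (6.82), which encode a hyaluronan link protein and a secreted matricellular protein.

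Hox genes rose for 45 of 52 members and fell for 0 (45 adjusted over the list alone). The list was not called with an estimated correlation (adjusted p = 0.193) and was called with the replicate block (adjusted p = 0.0417). *hoxb9.S* went from 0.497 to 60 ± 26 CPM, with 78.7 in replicate 1 and 41.3 in replicate 2, and *hoxa9.S* from 0 counts to 6.97 CPM, at least 85.9-fold higher. Anterior neural genes rose for 28 of 42 and fell for 5 (30 and 5 adjusted over the list alone, adjusted p = 0.256 with an estimated correlation), with the midbrain-hindbrain gene *pax2.L* at 23.5 CPM against 0.693. The cement gland list had 9 of 14 rising and 0 falling (10 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), and its marker *agr2.L* reached 353 ± 67 from 0.929 ± 1.1 (8.19 ± 1.26).

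Ribosomal protein list members rose for 118 of 127 and fell for 1 (119 and 1 adjusted over the list alone, 3 falling with the replicate block). The list was not called with an estimated correlation (adjusted p = 0.0951). Of its 117 members that are ribosomal proteins 113 rose and 0 fell. The other 10, which its name pattern let in, are *rps6k* kinase genes and *rps19bp1*, with the fallen member *rps6kc1.L* among them (adjusted p = 0.0891 without DMZ stage 11 replicate 2, 0.112 without stage 18 replicate 2 and 0.0758 with L and S counts summed). *rps9.L* went from 38.2 ± 0.45 to 141 ± 3.9 CPM (1.88 ± 0.15). Maternal transcripts fell for 38 of 59 and rose for 3 (43 and 3 adjusted over the list alone). The list was not called with an estimated correlation (adjusted p = 0.0644) but was with the replicate block (adjusted p = 0.0417). The risen members, named after their values were seen, were *trim36.L*, *h1f0.S* and *rtn3.S*. With L and S counts summed, *h1f0.S* lost its call (log2 fold change 0.26, adjusted p = 0.602) and *rtn3.S* turned to -0.20 (adjusted p = 0.281). *rtn3.S* also lost its call without DMZ stage 11 replicate 1 (adjusted p = 0.0695) or stage 18 replicate 2 (0.0681). Cell cycle genes fell for 31 of 60 and rose for 6 (32 and 8 adjusted over the list alone, 11 rising with the replicate block, adjusted p = 0.0644 with an estimated correlation). *wee2.S*, an oocyte and embryonic Wee1 kinase gene, fell by 6.01 on the log2 scale, and the cyclin gene *ccne2.L* went from 441 ± 35 to 109 ± 3.3 (-2.02 ± 0.15). Nodal genes fell for 20 of 31 and rose for 3 (20 and 4 adjusted over the list alone, adjusted p = 0.202 with an estimated correlation).

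Planar cell polarity genes went both ways, with 12 rising and 15 falling of 57 (12 and 16 adjusted over the list alone, adjusted p = 0.814 with an estimated correlation). *wnt11b.L* fell from 278 ± 50 to 59.7 ± 26 CPM (-2.22 ± 0.35), *prickle1.L* from 228 ± 43 to 83.6 ± 15 (-1.45 ± 0.24) and *fzd7.L* from 899 ± 24 to 404 ± 30 (-1.16 ± 0.19, adjusted p = 0.000196). *wnt5a.S* rose from 2.85 ± 0.14 to 13.4 ± 1.7 (2.24 ± 0.46), and *vangl2.L* stayed at 216 ± 57 and 213 ± 16 (adjusted p = 0.955). Among cadherins, *cdh3.S* fell from 419 ± 34 to 139 ± 19 (-1.59 ± 0.12) and the neural cadherin gene *cdh2.S* rose from 24.7 ± 5.6 to 106 ± 3 (2.09 ± 0.44). *chrd.L* was at 386 ± 140 and 385 ± 15 (adjusted p = 0.997). *t.S* fell from 374 ± 120 to 62.7 ± 22 (-2.58 ± 0.44), and the keratin gene *krt12.S* rose from 119 ± 110 to 997 ± 9.3 (3.06 ± 0.72). The dorsal organizer (7 rising and 11 falling of 33, 7 and 14 adjusted over the list alone, adjusted p = 0.901), pan-mesoderm (11 and 15 of 41, 13 and 15 adjusted over the list alone, adjusted p = 0.92) and FGF (6 and 15 of 32, also 6 and 15 adjusted over the list alone, adjusted p = 0.615) lists were not called with an estimated correlation.

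Over all genes 6543 were higher and 6131 lower at stage 18, and 8366 of 12674 calls were left against a fold of 1.5. Leaving out a library gave 8890 to 10498 calls. The larger direction turned with upper quartile scaling (6138 higher and 6453 lower) and without DMZ stage 11 replicate 1 (5237 and 5261) or 2 (4567 and 4624).

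**Figure D4:**
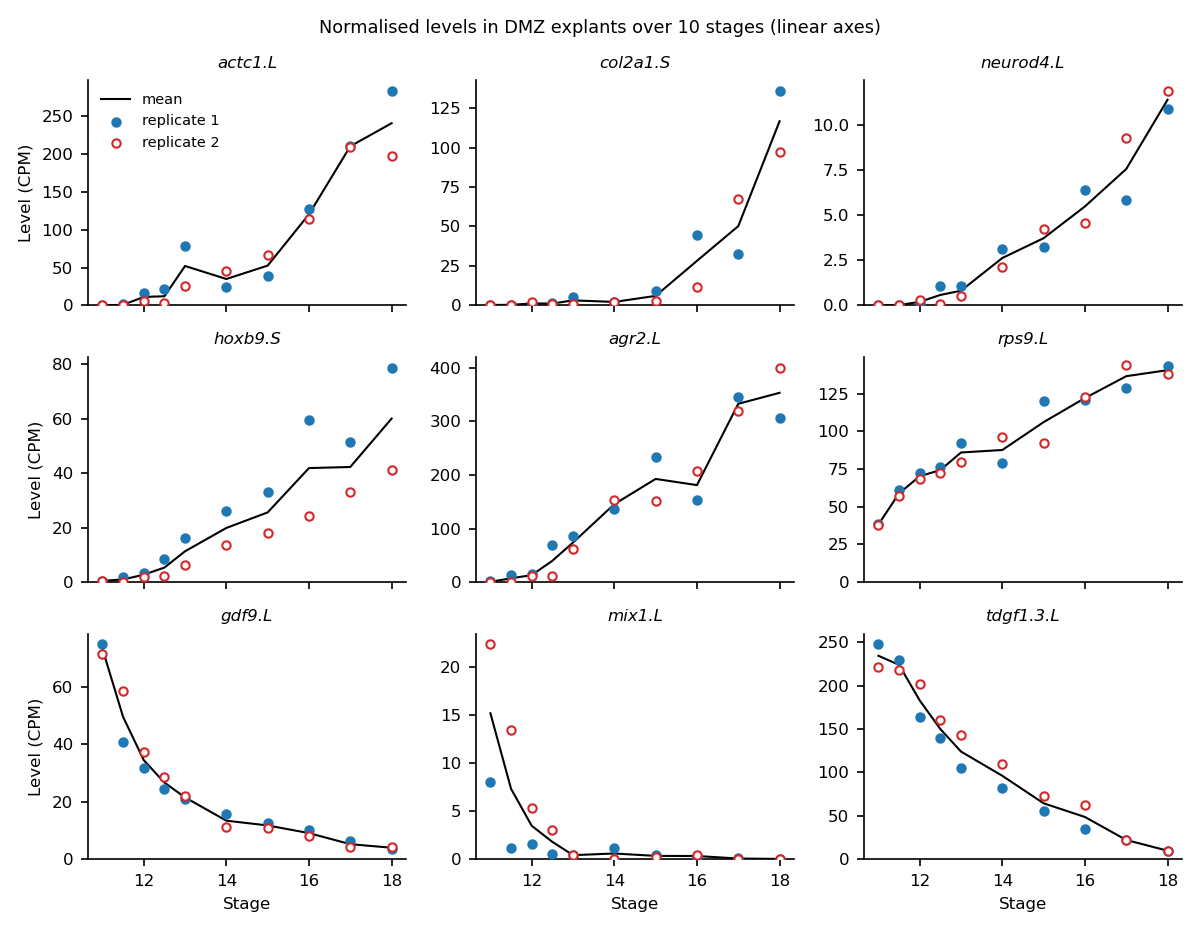
Levels of 9 genes in CPM on linear axes against stage from 11 to 18 in DMZ explants, with filled blue points for replicate 1, open red points for replicate 2 and a line through the means. *actc1.L* went from 0.0678 to 241 CPM and *gdf9.L* from 73.1 to 3.95, and at stage 11.5 replicate 2 lay above replicate 1 for *mix1.L*.

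Between stages 11 and 14, the first part of the course, regional genes of the neural plate were among those that rose. *six3.L*, a homeobox gene of the forebrain and eye field, rose from 0.507 to 99.8 ± 69 CPM (7.79 ± 1.22, adjusted p = 0.000587) and *pax6.L* rose by 5.66 on the log2 scale to 72.5 ± 22 (adjusted p = 0.00027). *actc1.L* was already at 34.9 ± 14 (8.33 ± 1.29), and the Hox gene *hoxb6.S* at 12.2 ± 1.4 against 1.52 ± 0.34 (2.96). *bix1.3.L* fell from 18.5 ± 13 to 0.402 (-5.51, adjusted p = 0.00297) and *gdf9.L* from 73.1 ± 2.4 to 13.3 (-2.46). Of the 30 lists 0 were called by camera with an estimated correlation, while the preset correlation called 19 and fry, which tests whether members move on balance 1 way, 15. Hox genes rose for 35 of 52 and fell for 0 (38 adjusted over the list alone, adjusted p = 0.223 with an estimated correlation). Ribosomal list members rose for 106 of 127 with 2 falling (114 and 2 adjusted over the list alone, 4 falling with the replicate block, adjusted p = 0.214 with an estimated correlation), and anterior neural genes rose for 19 of 42 with 0 falling (19 and 1 adjusted over the list alone, 4 falling with the replicate block and 2 with DESeq2, adjusted p = 0.284 with an estimated correlation). Maternal transcripts fell for 29 of 59 and rose for 2 (36 and 2 adjusted over the list alone, adjusted p = 0.166 with an estimated correlation). The falling ribosomal list members were the kinase genes *rps6kc1.L* and *rps6kc1.S*, named after their values were seen. Both lost their calls without DMZ stage 11 replicate 2 (adjusted p = 0.0542 and 0.129) or stage 14 replicate 2 (0.0615 and 0.0826), and *rps6kc1.S* without stage 14 replicate 1 (0.0884). In total 3930 were higher and 4076 lower. The 8006 calls became 3526 against a fold of 1.5 and 4353 when only these 4 libraries were fitted. They became 3838 without DMZ stage 11 replicate 2, and 4369 and 4381 without DMZ stage 14 replicate 1 or 2, where more were higher than lower (2350 and 2019, and 2242 and 2139), as with L and S counts summed (3311 and 3068).

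Between stages 14 and 18, the second part, some muscle and neuronal genes rose. The troponin gene *tnnt3.L* went from 1.29 to 30.6 CPM (4.56, adjusted p = 0.00228). *xirp1.L*, which encodes an actin-binding protein of striated muscle, rose from 0.0592 to 12.9 ± 3 (7.53 ± 1, adjusted p = 0.000816), *col2a1.S* from 2.17 to 116 ± 27 (5.74) and *tubb2b.S* from 5.34 to 59.4 ± 12 (3.48). *pou5f3.2.L*, a pluripotency factor gene, fell from 249 ± 17 to 12.3 (-4.34 ± 0.61, adjusted p = 0.00112), *pou5f3.1.L* from 983 to 163 (-2.59) and *bmp7.2.L* from 106 ± 39 to 10.7 ± 2.9 (-3.31 ± 0.38). Neuronal differentiation genes rose for 8 of 42 and fell for 0 (17 rising with the replicate block, 15 and 1 adjusted over the list alone, camera adjusted p = 0.0267, 0.0329 with the block). Skeletal muscle genes rose for 19 of 40 and fell for 0 (23 adjusted over the list alone, camera adjusted p = 0.0328). Cell cycle genes fell for 11 of 60 and rose for 0 (21 falling with the replicate block, 17 adjusted over the list alone, camera adjusted p = 0.0328), for example *cdt1.S* (-0.86). The muscle and cell cycle lists were not called with the replicate block (adjusted p = 0.0967 for each). Of 52 Hox genes edgeR called 0 in either direction, and 15 were higher at an unadjusted p under 0.05. DESeq2 called 0, and edgeR with the replicate block called 14 higher and 0 lower (0 adjusted over the list alone without the block, adjusted p = 0.552 with an estimated correlation, 0.0967 with the block as well). Ribosomal list members rose for 23 of 127 and fell for 0 (93 rising with the replicate block, 40 with DESeq2, 62 adjusted over the list alone, adjusted p = 0.415 with an estimated correlation). There were 1236 higher and 1152 lower genes (51.8% higher). Upper quartile scaling gave 1108 and 1529 (42% higher), and the larger direction also turned with the stricter filter (1194 and 1260), with every library thinned (786 and 884), and without DMZ stage 14 replicate 1 (346 and 438) or 2 (182 and 317). The 2388 calls became 5401 with the replicate block, 3680 with DESeq2 and 607 against a fold of 1.5. They became 423 and 837 without DMZ stage 18 replicate 2 or 1, and 499 and 784 without DMZ stage 14 replicate 2 or 1.

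Each stage of the course was also compared with the one before it. edgeR called 0 genes in each of the 9 neighbouring steps, and the genes with an unadjusted p under 0.05 numbered 2014 from stage 11 to 11.5 and between 336 and 855 in the other steps. Those other steps held a smaller share of the 31349 tested genes than the 0.05 expected with no change, so the test was cautious there. Replicate 2 also lay earlier on the replicate 1 course by 0.7 to 1.58 stage steps at stages 11.5 to 14, about the size of the step tested. The 0 calls therefore do not show that levels stayed the same. DESeq2 called 22 genes from stage 11 to 11.5, among them the neural crest and mesoderm gene *twist1.L* (2.97), *tbx6.S* (3.25) and *sox9.L* (1.47). It called 2 from 11.5 to 12 (*actc1.L*, 3.94, and an unnamed model). There were 3 from 16 to 17 (*snai2.L*, 1.83, *klhl40.L*, 1.47, and an unnamed model) and 3 from 17 to 18 (*tdgf1.3.L*, -1.21, *snx31.S*, -1.35, and the same unnamed model), and 0 in the other steps. These genes were named after their values were seen. Without DMZ stage 11.5 replicate 2, edgeR called 4 genes from stage 11 to 11.5, *lrat.S*, *krt8.S*, *mn1.S* and an unnamed model.

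The test of any change over the 10 stages called 9404 genes (14297 with the replicate block). The named genes of largest range were the myosin heavy chain gene *myh8* (0.115 to 192 ± 13 CPM between stages 11 and 18, adjusted p = 3.75e-05), *col2a1.L* (0.277 to 229, adjusted p = 5.14e-05), *actc1.L* (adjusted p = 3.3e-05), *atp2a1.L* (adjusted p = 3.18e-06), *agr2.L* (adjusted p = 0.000596) and the mucin gene *muc2* (0.847 ± 0.3 at stage 11.5 and 483 ± 8.6 at stage 18, adjusted p = 3.14e-05). The authors' deposited table lists 13913 gene models with a cluster, with adjusted p-values up to 0.000999685 and no label for what they test. Of these, 9079 (65.3%) were called here in the test of any change and 12295 (88.4%) in at least 1 of the 7 main tests. The test of any change called 325 that the authors' deposited table does not list. Of its 5 clusters, the second (4858 models) holds 39 of 60 maternal transcripts and 31 of 60 cell cycle genes. In the authors' deposited table, the fourth cluster (4143 models) holds 117 of 127 ribosomal list members and 36 of 52 Hox genes, and the fifth (2228 models) 15 of 40 muscle genes.

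Genes that set the regions apart at stage 11 were followed between stages 12 and 18 of the DMZ, which share no library with stage 11. Of the 701 genes higher in the DMZ than in the VMZ, 147 fell (21%) and 106 rose (15.1%), and of the 781 higher in the DMZ than in the cap, 186 fell (23.8%) and 92 rose (11.8%). Of the 284 higher in the VMZ, 93 rose (32.7%) and 26 fell (9.15%), and of the 225 higher in the cap, 45 rose (20%) and 30 fell (13.3%). Among all tested genes 13.9% rose and 13.3% fell. The difference between these shares was not tested. With the replicate block, 352 of 1079 VMZ-higher genes rose (32.6%) and 177 fell (16.4%), 120 of 497 cap-higher genes rose (24.1%) and 113 fell (22.7%), and 20.3% and 19.3% of all genes did so. With it, 404 of 1635 genes higher in the DMZ than in the VMZ fell (24.7%) and 325 rose (19.9%), and of the 1195 higher than in the cap 343 fell (28.7%) and 200 rose (16.7%). The 8535 calls from stage 12 to 18 became 3906 without DMZ stage 12 replicate 2, 5213 and 4757 without DMZ stage 18 replicate 1 or 2, and 4368 against a fold of 1.5. With every library thinned to the smallest total, an alternative chosen after seeing the data, the share of VMZ-higher genes that rose was 21.1%.

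Homeologs were compared as the ratio of L to S counts in each library. Of 5024 pairs 56.2% had more L than S counts on average (median log2 ratio 0.24). Between stages 11 and 18 the ratio changed in 1886 pairs (37.5%, limma with Benjamini-Hochberg adjustment), toward L in 1014 and toward S in 872. Both copies were called in 1409 pairs, in the same direction in 1257 and in opposite directions in 152. The pairs named here, all from those 152, were chosen after their values were seen. *cdk9*, which encodes the kinase of the elongation factor P-TEFb, fell for L (-2.41, adjusted p = 9.36e-05) and rose for S (0.87, adjusted p = 0.000855), and *serpinh1*, the collagen chaperone gene, changed by -0.75 for L and 4.72 for S. *cd63*, a tetraspanin gene, rose for L (0.56) and fell for S (-1.22), and *cbs*, the cystathionine beta-synthase gene, changed by -0.95 for L and 0.73 for S (adjusted p = 0.011 and 0.0403). Reads of similar copies could have been split between them in counting.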

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

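The test of libraries thinned to the smallest total was chosen after the data were seen. The called genes for DMZ vs VMZ, DMZ vs animal cap and VMZ vs animal cap numbered 985, 1006 and 324, and for DMZ stages 18 vs 11, 14 vs 11 and 18 vs 14 they numbered 12674, 8006 and 2388. With the replicate block the counts were 2714, 1692 and 867 for the regions, 5401 for stage 18 vs 14 and 14297 (against 9404) for any change. DESeq2 gave 2251, 1645, 902 and 3680 for the same 4 comparisons, and 22, 2, 3 and 3 for the steps 11.5 vs 11, 12 vs 11.5, 17 vs 16 and 18 vs 17, where edgeR called 0. Against a fold of 1.5 the 6 counts were 285, 513, 159, 8366, 3526 and 607. Fitting only the groups compared, which leaves fewer samples to estimate the spread, gave 0 (2510 at an unadjusted p under 0.05), 193, 0 (1600 unadjusted) and, for stage 14 vs 11, 4353. Leaving out 1 library, where the lone library is assumed to vary like the other groups, gave 210 to 1434, 489 to 744, 133 to 352, 8890 to 10498, 3838 to 6711 and 423 to 837 calls, 0 to 4 for stage 11.5 vs 11, 0 for each other step and 7414 to 9972 for any change. The share of VMZ-higher genes that rose from stage 12 to 18 was 21.1% after thinning against 32.7%. For the changes other than fewer samples or a stricter threshold the cause was not tested.

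Lists called with an estimated correlation numbered 5, 14, 3, 1, 0 and 3 in the 6 comparisons. The preset correlation called 16, 22, 22, 16, 19 and 16, and each list called with an estimated correlation was among them. fry called 11, 16, 9, 21, 15 and 7, and the replicate block 4, 13, 6, 3, 0 and 1. The block changed no other call than those given beside the results.

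Directions reversed for genes that were not called, and for *rtn3.S*, which was. For stage 18 vs 11, *chrd.L* (-0.003 on the log2 scale) was at 0.02 with the replicate block, 0.061 with L and S summed, 0.017 with only the groups compared, 0.006 thinned, and between -0.328 and 0.415 with 1 library left out. *vangl2.L* was at 0.156 with L and S summed and between -0.264 and 0.278 with 1 library left out. Leaving out VMZ replicate 2 or 1, DMZ vs VMZ gave -0.044 or 0.526 for *prickle1.L* and -0.093 or 0.786 for *wnt11b.L*, and VMZ vs animal cap gave 0.273 or -1.265 for *chrd.L* (0.078 thinned). *rtn3.S* was at -0.20 with L and S summed, where the other copy is added. The library of 7.38 M counts limits genes of low level at stage 11.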

Other observations

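In 4 more gene lists, none of them called by camera with an estimated correlation, some members rose and others fell in DMZ explants between stages 11 and 18. In the presomitic list only 1 fell. Neural crest genes rose for 12 of 32 and fell for 3 (also 12 and 3 adjusted over the list alone, adjusted p = 0.407 with an estimated correlation), with *twist1.L* at 8.88 ± 0.19 CPM against 0.456 ± 0.26 and *sox9.L* at 10.4 ± 1.1 against 1.57 ± 0.31 (n = 2). Presomitic genes rose for 18 of 42 and fell for 1 (also 18 and 1 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation), with *tbx6.S* at 24.4 ± 3.5 against 0.507 ± 0.19 and *tcf15.L* at 16.1 ± 1 against 1.53 ± 0.19. Outside these 4 lists, the retinoic acid hydroxylase gene *cyp26c1.L* of the retinoic acid list went from 7.57 ± 1.8 to 194 ± 52. Stress and immediate early genes fell for 24 of 48 and rose for 7 (24 and 8 adjusted over the list alone, adjusted p = 0.407 with an estimated correlation), with *fos.S* at 4.42 ± 0.31 against 30.9 ± 4.8. Epidermal genes rose for 16 of 51 and fell for 8 (also 16 and 8 adjusted over the list alone, adjusted p = 0.603 with an estimated correlation), among them the keratin gene *krt8.S* (2430 ± 380 against 333 ± 19) and the tight junction gene *ocln.S*, which fell (58.6 ± 0.17 against 208 ± 8.1).

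In the patterns that follow, the tests of swapped labels and of an earlier developmental position as the source of the endoderm difference were chosen after the result was seen. The test of low counts in homeolog pairs was chosen after the pattern was seen and before its own result was.

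DMZ libraries of replicate 2 lay earlier on the course of replicate 1 than their own stage by 0.7 to 1.58 stage steps at stages 11.5 to 14 (1.31 on average at 11.5 to 13, 1.41 at 14), by 0.4 and 0.59 at stages 15 and 16 and by 0.2 at stage 18. They lay later by 0.64 at stage 17 (lag -0.64) and at a lag of -0.11 at stage 11, where the course of replicate 1 begins. Placed on the course of replicate 2, replicate 1 lay later by 1.49 to 1.62 steps at stages 11 to 13, by 0.63 at stage 14, by 0.54 and 0.53 at stages 15 and 16, and by -0.34 and -0.38 at stages 17 and 18. Thinning every library to the smallest total left a mean lag of 1.29 at stages 11.5 to 13, which argues against depth. Of the neighbouring replicate 2 libraries 0 were out of stage order, which argues against swapped labels among them. Across genes, the difference between replicates correlated with the change from stage 12 to 13 (r = 0.374, genes not being independent replicates), which argues against a difference wholly unrelated to developmental time. A fixed difference beside the lag is not excluded, since replicate 1 lay above replicate 2 on the second principal component in every group. The hypothesis that the replicate 2 explants developed later relative to the siblings used for staging may account for the lag and was not tested further.

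Endoderm list members were higher in replicate 2 than in replicate 1 of the DMZ at stages 11 and 11.5 (median log2 difference 2.58), and thinning left 2.16, which argues against depth. The difference was -0.16 at stage 12, 1.64 at stage 12.5 and between -0.55 and 0.31 from stage 13 on, and at stage 11 it was -1.07 in the VMZ and 0.54 in the animal cap. At the position of replicate 1 on the replicate 2 course (2.62 and 3.49 steps for stages 11 and 11.5), the replicate 2 level lay above that of replicate 1 by a median of 1.31. This value depends on the libraries it was interpolated between, since replicate 2 lay above replicate 1 of stage 11 by 2.92 at stage 11.5 and by 0.908 at stage 12. Of the 32 members 17 are also in other lists, and among the most abundant at stage 11, *vegt.L* stood at 154 CPM in replicate 1 and 273 in replicate 2, *mixer.L* at 2.41 and 23.9, and *sox17a.S* at 0.576 and 11.3 (at stage 11.5, 44.4 and 276, 0.916 and 19.1, and 0.515 and 11.9), while *a2m.S* went the other way, at 883 and 802 (911 and 751). An earlier position, a difference between clutches, between single collections of explants or in the number of endoderm cells stays open.

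Of the homeolog pairs, 152 had L and S members called in opposite directions between stages 11 and 18. Reads moved from one copy to the other in counting could make the gain of one match the loss of the other, and this held for 19 pairs (12.5%). The match is forced only where the summed level of both copies stayed the same, which was not checked. The test therefore cannot decide whether read assignment was the source. From stage 12 to 17, which share no library with stages 11 and 18, the ratio moved the same way in all 152 pairs (100%). Among pairs without a called ratio change 75.8% did so, which already lies above the 50% expected of noise alone. The ratio changes of the 152 pairs were thus repeated in other libraries. Either copy alone can move the ratio, so this test cannot decide whether low counts of the other copy made the directions opposite. The hypothesis that some copies are regulated separately may apply to some of these pairs, and it was not tested here.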
